A study of Mus musculus with 3 samples.

How the data were processed

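The samples were 3 single-cell RNA libraries of bone marrow cells from C57BL/6 mice, sorted for the leukocyte antigen CD45 and for Gr1. Gr1 is an epitope carried by neutrophils and, more weakly, by some monocytes and other marrow cells. A single library came from a sham-operated male mouse, another from an orchiectomized male mouse and the third from a female mouse of matched age, with the marrow of the males taken 3 weeks after the operation. For the female the labels give a sham operation, which the protocol does not mention, so whether it was operated on is not settled. Libraries were made with a droplet-based 3′ kit, and per the submitters' processing notes the reads were processed with Cell Ranger on genome build mm10. The header of each count matrix gives the software version 3.0.1.

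The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalization. Barcodes had been called as cells before deposit, and the lowest total of any barcode was 500 UMIs. All 3 matrices list the same 27998 genes, 65 of which carry a symbol that another gene also carries. Gene coordinates were read from GENCODE M21, in which 27645 of the 27998 gene identifiers were found.

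The sham male library held 13731 barcodes and 77060165 UMIs. The orchiectomized male library held 9796 barcodes and 47373142 UMIs. The female library held 12485 barcodes and 70196205 UMIs. Barcodes were kept with at least 500 UMIs, at least 200 genes and under 10% mitochondrial UMIs, which left 13633, 9638 and 12256 in that order. Doublets were scored per library with Scrublet as provided in scanpy, simulating 2 doublets per cell. The automatic threshold found no doublets in the sham male library, where it lay at 0.573, so a common score threshold of 0.135 was used in all libraries, the mean of the automatic thresholds of the other libraries. That choice was made after the data were examined. It removed 7.87% of cells in the sham male, 8.39% in the orchiectomized male and 9.18% in the female library.

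The remaining cells were clustered together without integration. UMIs were scaled to 10000 per cell and log-transformed, and the 2000 most variable genes were used, without the sex-linked genes and without the S phase and G2/M phase lists. The clustering used 30 principal components, 20 neighbours and the Leiden algorithm at resolution 1 with seed 1, which gave 23 clusters. Clusters were named from 17 lists of marker genes fixed before the data were examined, with a minimum of 3 markers at 1.5-fold and a score of at least 0.3. Clusters with a median doublet score over 0.08, or whose leading genes belonged to another class, were left without a name. The names are rebuilt from marker genes and are not the study's own. Software was Python 3.11.15 with scanpy 1.11.5, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2, scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3, with matplotlib 3.10.9 for the plots.

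The comparisons were the orchiectomized male against the sham male library and the female against the sham male library, with the orchiectomized male against the female library beside them. With 1 library per group no test was run. Shares of cells carry exact Clopper-Pearson 95% intervals, and UMI sums, ratios and folds carry exact Poisson 95% intervals. For genes, UMIs were summed per class and library and divided by the total UMIs of that class (CPM), and a pseudocount of 1 CPM was added before taking log2 ratios. The folds printed for single genes are ratios of CPM without the pseudocount. Shares of cells with a UMI of Mki67, Top2a or Pcna were taken after drawing each cell down to 1000 UMIs, with shallower cells left out.

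Gene lists fixed before the data were examined covered S phase, G2/M phase, primary, secondary and tertiary granule genes, mature neutrophil genes, granulopoiesis transcription factors, androgen and shared steroid receptor response, androgen and growth factor signalling, interferon response, NF-kB inflammatory genes, immediate early and stress genes, NADPH oxidase, NET and histone handling, glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, mitochondrial transcripts, marrow retention and egress, MHC and antigen presentation, histones, and apoptosis and survival. Female-linked and Y-linked lists served to check the sex in the labels. A member of a list was measured in a class with at least 20 UMIs summed over the libraries compared. Each list is described by the median log2 ratio of its measured members, by the number past an upper limit of 1.25-fold and a lower limit of 0.8-fold, and by the percentile of its median among 10000 random lists matched on expression. That percentile describes these libraries and is no test across mice. Lists of clock genes of the phase of Per1, clock genes of the opposite phase and glucocorticoid response genes were added after the data were examined and are used in the closing section only.

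Genes to name were fixed by a rule set before the data were examined. Among genes with at least 30 UMIs in each of the 3 neutrophil classes and with a log2 ratio of the same sign in all of them, the 12 with the highest and the 12 with the lowest mean log2 ratio were taken per comparison, from 6894 eligible genes for the orchiectomized male and 7298 for the female library. The female-linked and Y-linked lists, mitochondrial transcripts, ribosomal protein genes and markers of other cell types were left out of this ranking, while X-linked genes outside these lists could be named. A fixed set of further genes was always followed, and within each list the 2 highest and 2 lowest members with at least 50 UMIs could be given as examples.

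The method was tested on simulated data with 200 altered genes among 8878 and 9215. In both comparisons, all 12 genes named higher and all 12 named lower were altered genes, and 94.7% and 94.5% of the intervals held the true fold, taken after scaling by total UMIs. That scaling moved folds away from those set, so that genes set at 3-fold were recovered at a median of 2.59-fold in the orchiectomized male and 2.92-fold in the female comparison, and genes set at 2-fold at 1.73-fold and 1.98-fold. The simulated counts were drawn from a single profile with counting error only, so coverage near 95% follows by construction. Differences between mice, clustering and doublets were not simulated. The altered genes were also chosen to carry more UMIs than the minimum of the naming rule, so genes near that minimum were not covered. The alternatives tried were 17 fixed before the data were examined and 5 added afterwards. They covered the filters on cells, the treatment of doublets, the clustering, the depth of thinning, the scaling and pseudocount, the minimum of UMIs, the members of the cycle lists and the cells counted in the denominator.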

Results

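The transcripts of single marrow cells carrying CD45 and Gr1 were counted in a sham-operated male, an orchiectomized male and a female mouse, with 1 library each. Orchiectomy removes the testes, the main source of androgen. The libraries held 77060165 UMIs (sham male), 47373142 UMIs (orchiectomized male) and 70196205 UMIs (female). After filtering, 12560, 8829 and 11131 cells were kept, with medians of 3928, 3522 and 3800 UMIs per cell. No replicate check was possible with 1 library per group, so the values describe these libraries, and their 95% intervals cover counting error only.

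Sex-linked transcripts matched the sex in the labels. Xist, the RNA that silences an X chromosome in female cells (ENSMUSG00000086503, mm10 chromosome X, 103460366 to 103483254), had 48940 UMIs in the female, 4 in the sham male and 0 in the orchiectomized male library. Its antisense partner Tsix had 778, 22 and 3 UMIs in that order. The Y-linked genes were read in both male libraries, with 2163 and 1616 UMIs of Ddx3y, 2312 and 2182 of Eif2s3y, 645 and 491 of Kdm5d and 651 and 465 of Uty in the sham and the orchiectomized male. The female library held 0 UMIs of Ddx3y, Eif2s3y and Kdm5d and 1 of Uty. No transcript checks the orchiectomy itself.

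The clusters, whose names are rebuilt from marker genes, gave a neutrophil series in all libraries. Precursor-like cells (cluster 6) were led by the primary granule genes Elane, Ms4a3 and Mpo. Immature-like cells (clusters 1, 2 and 4) were led by secondary granule and related genes such as Chil3, Camp, Ngp, Ltf and Ly6g. Mature-like cells comprised clusters 0 and 5, led by Gm5483, Clec4d, Retnlg and Mmp8, and cluster 7, led by Il1b and with the interferon genes Rsad2 and Oasl2 among its first 10. The other named classes were progenitor-like, monocyte-like, conventional and plasmacytoid dendritic-like, T, B and NK cell-like, basophil or mast-like and macrophage-like cells. Unnamed clusters held 7.33% of the sham male, 1.72% of the orchiectomized male and 3.01% of the female cells. Of these, clusters 15 and 17, like cluster 22 with high doublet scores, held 3.37% and 2.19% of the sham male, 0.476% and 0.227% of the orchiectomized male and 0.818% and 0.620% of the female cells. Of the other unnamed cells, cluster 16, led by Ace and Apoe, held 1.61%, 0.997% and 1.56%, and cluster 22, led by plasma cell genes, held 0.167%, 0.0227% and 0.00898%.

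The androgen receptor gene Ar (ENSMUSG00000046532, chromosome X, 98148769 to 98323215) was hardly read in the neutrophil series. All kept cells together held 23 UMIs in the sham male, 13 in the orchiectomized male and 23 in the female library. Of these, 12, 8 and 12 lay in T cell-like cells and 7, 4 and 3 in plasmacytoid dendritic-like cells. Precursor-like cells held 0 UMIs in all 3 libraries, over 789, 318 and 575 cells, which allows a share of cells with an Ar UMI of up to 0.466%, 1.15% and 0.639%. Immature-like cells held 0, 1 and 0 UMIs and mature-like cells held none in the 3 libraries. Ar was therefore not detectable at this depth in precursor-like cells of these libraries, which leaves open whether they carry the receptor.

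The comparison of the orchiectomized with the sham-operated male addresses how loss of testicular androgen relates to neutrophil precursors and their cycling. The orchiectomized male library had a lower share of precursor-like cells and a share of mature-like cells 2.38 times that of the sham male. Within precursor-like cells, transcripts of S phase genes were higher. Those of G2/M genes were level there when scaled by total UMIs and lower with size factors. The direction of their joint sum in precursor-like cells therefore depended on the scaling. In cluster 2, the most cycling of the immature-like clusters, the S phase, G2/M and joint sums were higher under both scalings. The joint ratio of cluster 2 was 1.125, or 1.032 with size factors. The other immature-like clusters had lower joint sums than in the sham male. The immediate early genes Junb and Jun and the steroid- and clock-responsive gene Per1 were higher through the neutrophil series, and the median of the interferon list was lower in every neutrophil class.

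Precursor-like cells made up 3.60% (3.22 to 4.01) of the orchiectomized male and 6.28% (5.86 to 6.72) of the sham male cells, a ratio of 0.573 (0.502 to 0.654). Progenitor-like cells, led by Mif and Cd34, made up 2.05% (1.76 to 2.37) and 3.68% (3.36 to 4.02), a ratio of 0.557 (0.467 to 0.663). Mature-like cells made up 34.7% (33.7 to 35.7) and 14.6% (14.0 to 15.2), a ratio of 2.38 (2.24 to 2.52). All 3 of their clusters were larger, cluster 0 with 20.8% against 8.26%, cluster 5 with 8.37% against 4.41% and cluster 7 with 5.53% against 1.93%. Immature-like cells made up 29.1% (28.2 to 30.1) and 30.9% (30.1 to 31.7). Of the 3 neutrophil classes together, 5.34% were precursor-like and 51.5% mature-like in the orchiectomized male, and 12.1% and 28.2% in the sham male.

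These shares depend on the Gr1 sort, on the floor of 500 UMIs and on what is counted. Median UMIs were 12625 in precursor-like and 827.5 in mature-like cells of the sham male, and 16255 and 1083 in the orchiectomized male. Of the mature-like cells, 59.7% of the sham male and 43.3% of the orchiectomized male had under 1000 UMIs, and doublet removal had taken 7.87% and 8.39% of all cells. With at least 1000 UMIs per cell, the ratio of the mature-like shares was 3.73. Without mature-like cells and doublet-like clusters in the denominator, the precursor-like ratio was 0.708, and with genes that differed between the libraries left out of the clustering it was 0.662. The order of the immature-like shares reversed under 5 alternatives.

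Cycling was read first from the summed UMIs of 45 S phase and 55 G2/M genes. In precursor-like cells, S and G2/M UMIs together were 121.5 (120.6 to 122.4) per 10000 UMIs in the orchiectomized and 116.3 (115.6 to 116.9) in the sham male, a ratio of 1.045 (1.035 to 1.055). This excess was below the shift of the median gene with at least 20 UMIs in both libraries, 1.071-fold, and with median-of-ratios size factors, run for the sums after the data were seen, the ratio was 0.976 (0.967 to 0.985). S phase UMIs were 41.1 against 35.3 per 10000, a ratio of 1.163 (1.144 to 1.182) and with size factors 1.086 (1.068 to 1.104), while G2/M UMIs were 80.4 against 80.9, a ratio of 0.994 (0.982 to 1.005) and with size factors 0.928 (0.917 to 0.939). Progenitor-like cells held 134.0 against 124.8 per 10000, a ratio of 1.074 and with size factors 1.037. Cluster 2, the most cycling of the immature-like clusters, with the granule genes Camp and Ngp and the transcription factor Cebpe among its leading genes, held 164.2 against 145.9 per 10000, a ratio of 1.125 (1.116 to 1.134) and with size factors 1.032 (1.024 to 1.040). The other immature-like clusters had lower sums than in the sham male, with ratios of 0.850 in cluster 1 and 0.931 in cluster 4, and the immature-like class as a whole was at 1.003 (0.996 to 1.010), or 0.952 with size factors. Cluster 2 made up 8.61% of the orchiectomized and 11.3% of the sham male cells. Over all kept cells the sum was 100.4 (100.1 to 100.7) against 103.4 (103.2 to 103.6), a ratio of 0.971 (0.967 to 0.975), which was 0.933 with size factors and 1.015 when mature-like cells and doublet-like clusters were left out.

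Cells with a UMI of Mki67, a marker of proliferating cells (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), gave a second reading at a common depth of 1000 UMIs. In precursor-like cells the share was 26.8% (22.0 to 32.1) in the orchiectomized and 23.8% (20.8 to 26.9) in the sham male, a difference within the intervals. At full depth it was 85.8% and 87.5%. Over all kept cells it was 12.96% (12.2 to 13.8) and 16.9% (16.2 to 17.6) after thinning, and 24.2% and 37.1% at full depth. Thinning left out 1622 and 1465 cells. Mature-like cells, taken as background, held 1.04% and 0.811% at median depths of 1083 and 827.5 UMIs before thinning. In precursor-like cells, Top2a shares were 25.6% and 24.3% and Pcna shares 19.9% and 18.6%.

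**Figure D1:**
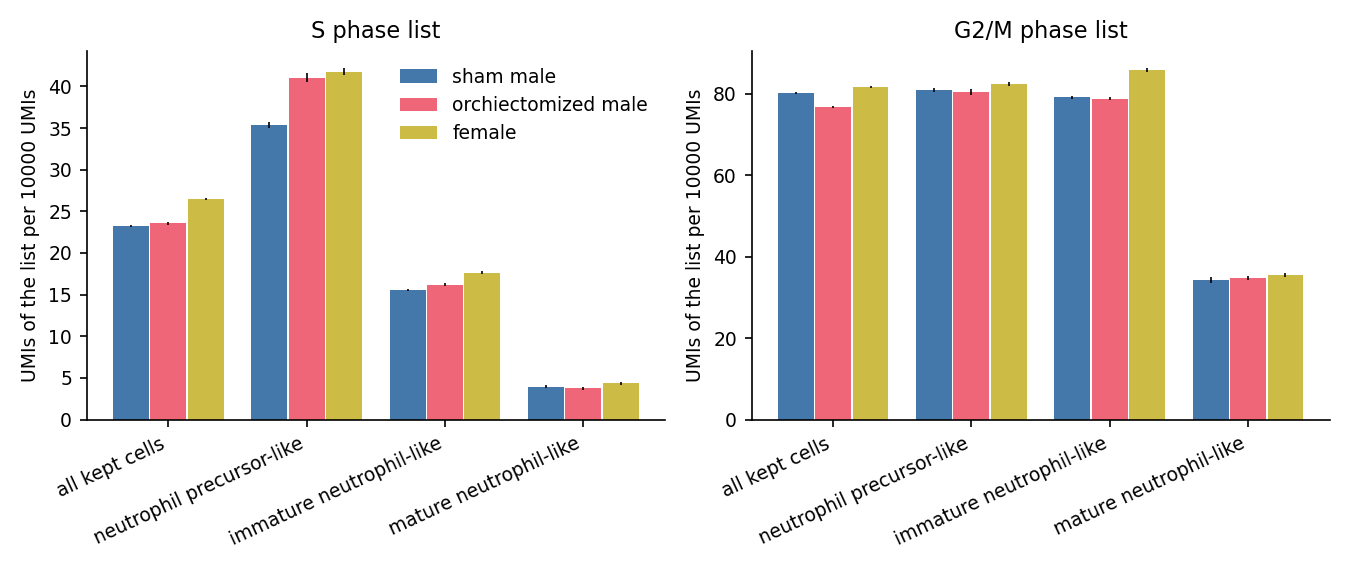
Summed UMIs of the S phase list and of the G2/M list per 10000 UMIs (vertical axis) in the 3 libraries, with exact Poisson 95% intervals as error bars. In precursor-like cells the S phase values, scaled by total UMIs, were 35.3 (sham male), 41.1 (orchiectomized male) and 41.8 (female).

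The scaling by total UMIs shifted all genes together, so list medians are best read against it. Over all measured genes, the median log2 ratio of the orchiectomized to the sham male was 0.087 in precursor-like, 0.062 in immature-like and −0.081 in mature-like cells. With median-of-ratios size factors the same medians lay between −0.0058 and −0.0048. Members of a list are counted past the upper or lower limit of fold given with the processing. Folds and medians of a class also depend on the clusters within it. Cluster 7, led by Il1b, held 488 of the 3065 mature-like cells of the orchiectomized male and 242 of the 1834 of the sham male.

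The cycle lists showed the same division as the sums. In precursor-like cells, the S phase list had a median log2 ratio of 0.23 (0.13 with size factors), above all random lists, with 12 of 45 members past the upper limit and 0 past the lower limit. Its highest members were the repair genes Ung, 1.70-fold (1.32 to 2.19), and Msh2, 1.51-fold (1.24 to 1.83), and Pcna, the sliding clamp of DNA polymerase, was at 267 against 203 CPM. Of the other cycle genes followed, Mcm5 was at 225 against 199.8, Mki67 at 321 against 301 and Top2a at 344 against 339.7 CPM, the last 2 changing direction with size factors. The G2/M list had a median of −0.046 there (−0.14 with size factors), with 0 of 55 members past the upper limit and 2 past the lower limit, and lay at −0.10 and −0.26 in immature-like and mature-like cells. The S phase medians of immature-like and mature-like cells, 0.024 and −0.053, both changed sign with size factors. The histone list had medians above 0 in all 3 classes, at 0.29, 0.23 and 0.19, with 30 of 65, 20 of 65 and 8 of 23 members past the upper limit, among them Hist1h3d at 2.06-fold (1.31 to 3.22) in precursor-like cells.

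Granule genes, several of which helped to draw the clusters, differed by stage. Primary granule genes had a median of 0.059 in precursor-like cells, which changed sign with size factors, −0.47 in immature-like and −0.42 in mature-like cells. In precursor-like cells, neutrophil elastase, Elane (ENSMUSG00000020125, chromosome 10, 79886247 to 79888215), was at 11384 against 9659 CPM, Mpo, myeloperoxidase, at 9101 against 7827, Prtn3 at 9265 against 9310.4, Ctsg at 2574 against 2268 and Fcnb at 1081 against 909.8. In immature-like cells Mpo was at 27.0 against 48.4 CPM, which lies below its 38.2 against 56.4 CPM in T cell-like cells, so that its level there is no higher than in cells of another lineage. Secondary granule genes had a median of −0.36 in precursor-like cells (8 of 14 past the lower limit), 0.055 in immature-like cells, which changed sign with size factors, and −0.25 in mature-like cells. In precursor-like cells Ltf was at 565 against 887 CPM, and in T cell-like cells at 717 against 1116 CPM. These T cell-like values include cells with over 1% of their UMIs from S100a8. A Ltf UMI was found in 68.2% and 77.3% of precursor-like cells, which are deeper, and in 37.6% and 36.5% of T cell-like cells. How much of the Ltf of precursor-like cells came from other cells therefore cannot be set apart. In immature-like cells Ltf, lactoferrin, was at 13111 against 10925 CPM, Camp at 53637 against 55296, Ngp at 56105 against 53986 and Lcn2 at 15149 against 15031, the last 2 changing direction with size factors for these small differences. Chil3, a chitinase-like protein, was 1.86-fold (1.85 to 1.88) there. Tertiary granule genes had medians of −0.22, 0.30 and 0.11. In precursor-like cells Retnlg, of this list, was at 174 against 302 CPM, below its 517 against 1271 CPM in T cell-like cells. Transcripts of other cells therefore cannot be set apart for late genes of precursor-like cells. The metalloproteinase genes Mmp25 and Mmp8 were 1.48-fold and 1.46-fold in immature-like cells, but Mmp8 was 0.467-fold (0.400 to 0.544) in precursor-like cells. The immature-like class was made up differently, since cluster 1, with Mmp8 and Mmp9 among its first 10 genes, held 986 of its 2572 cells in the orchiectomized male. In the sham male cluster 1 held 1213 of 3880.

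The mature neutrophil list had medians of −0.23 in precursor-like cells, with 9 of 21 members past the lower limit, 0.0014 in immature-like cells, which changed sign with size factors, and 0.27 in mature-like cells, with 9 of 24 past the upper limit. In mature-like cells Clec4d was 1.80-fold (1.67 to 1.94), Il1b, interleukin 1 beta, was at 845 against 523 CPM, Retnlg at 28267 against 18614, the chemokine receptor Cxcr2 at 1745 against 1317, Cxcr4 at 410 against 401 and the G-CSF receptor Csf3r at 2232 against 2104. In immature-like cells Il1b was 0.252-fold (0.183 to 0.341). In the same libraries, cells of other types held more neutrophil transcripts in the sham male, where 16.7% of T cell-like cells had over 1% of their UMIs from S100a8, against 5.85% in the orchiectomized male. The granulopoiesis transcription factors had medians of 0.031, which changed sign with size factors, 0.20 and 0.075. Among them, Cebpa was 1.51-fold (1.34 to 1.70) and Myc 1.43-fold in precursor-like cells, Gfi1 was at 176 against 156 CPM there, Cebpe at 741 against 697 CPM in immature-like cells, and Cebpb 2.50-fold (2.37 to 2.64) in mature-like cells.

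The immediate early and stress list had medians above 0 in all 3 classes, at 0.30, 0.28 and 0.55, with 11 of 23, 11 of 24 and 15 of 23 members past the upper limit. Junb was 2.29-fold (2.18 to 2.41) in mature-like cells, at 1556 against 680 CPM, and Jun 2.56-fold (1.75 to 3.77) in precursor-like cells, while Dusp1 was 0.599-fold in immature-like cells. NF-kB inflammatory genes had medians of −0.063, 0.037 and 0.16, the second of which changed sign with size factors, and the prostaglandin synthase Ptgs2 was 2.43-fold (1.68 to 3.60) in mature-like cells. Interferon response genes had medians of −0.21, −0.17 and −0.19, with 14 of 30, 12 of 32 and 15 of 32 members past the lower limit. Among them, Slfn4 was 0.482-fold (0.402 to 0.576) in precursor-like cells and Gbp2 0.384-fold (0.239 to 0.595) in immature-like cells, whereas the chemokine gene Cxcl10 was 7.15-fold (4.54 to 11.6) in precursor-like cells, at 16.7 against 2.34 CPM, and 0.0883-fold (0.0269 to 0.228) in mature-like cells.

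The list of androgen and shared steroid receptor response genes had medians of 0.21 in precursor-like cells (0.13 with size factors; 5 of 18 past the upper limit, 1 past the lower limit), 0.14 in immature-like cells and −0.085 in mature-like cells. Its members went apart in mature-like cells, where Per1 was 5.53-fold (3.93 to 7.98), Tsc22d3, a glucocorticoid-induced gene, at 498 against 335 CPM, and Fkbp5, an androgen- and glucocorticoid-induced chaperone gene, at 80.7 against 140 CPM. Androgen and growth factor signalling genes had medians of 0.17, 0.073 and 0.15, the second of which changed sign with size factors, with the kinase gene Pim1 1.71-fold in mature-like cells.

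Transcripts of the mitochondrial genome had medians of 0.29, 0.12 and −0.88, and all 12 measured in mature-like cells were past the lower limit, among them mt-Co1 at 0.679-fold (0.651 to 0.708). Mature-like cells were shallower in the sham male, with a median of 827.5 against 1083 UMIs. The median mitochondrial share of all its kept cells was 1.07%, against 0.67%. Whether cell quality plays a part was not tested. Nuclear oxidative phosphorylation genes had medians of −0.033, −0.12 and −0.099. Cytosolic ribosomal protein genes had medians of 0.081, which changed sign with size factors, −0.12 and 0.082. Glycolysis genes had medians of 0.075, 0.12 and −0.031, with the first and the last changing sign with size factors, and Pgk1 was 1.67-fold in immature-like cells. NADPH oxidase genes had medians of −0.084, 0.12 and 0.077. NET and histone handling genes had medians of 0.10, 0.0060 and −0.34, the second changing sign with size factors and the third turning positive under 3 alternatives. Marrow retention and egress genes had medians of −0.098, 0.15 and 0.066, with Cxcr4 1.28-fold in precursor-like and 1.30-fold in immature-like cells. MHC and antigen presentation genes had medians of −0.017, −0.061 and −0.14. Apoptosis and survival genes had medians of 0.00046, 0.0043 and −0.0010, all of which changed sign with size factors, and the survival gene Mcl1 was 1.45-fold in mature-like cells.

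By the fixed rule, 12 genes were named higher in the orchiectomized male. Per1 (ENSMUSG00000020893, chromosome 11, 69095217 to 69109960), a clock gene that glucocorticoids also induce, came first at 2.01-fold (1.38 to 2.92) in precursor-like and 2.01-fold in immature-like cells. The immediate early genes Junb (ENSMUSG00000052837, chromosome 8, 84974484 to 84978718), Jun, Ier3 and Zfp36 lay between 1.28-fold and 2.56-fold in the 3 classes. Trib1, a regulator of the C/EBP factors, was 2.28-fold and 2.19-fold in immature-like and mature-like cells. The others were Mtus2, Acot1, Ero1lb, Jag1, Mitf and Cd14, between 1.33-fold and 4.20-fold, most at a few CPM with wide intervals.

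The 12 named lower included Eps8l1 (ENSMUSG00000006154, chromosome 7, 4460674 to 4480487) at 0.280-fold (0.0974 to 0.661), 0.518-fold and 0.286-fold in precursor-like, immature-like and mature-like cells. Wfdc17 (chromosome 11, 83703991 to 83706268), which also leads a doublet-like and a monocyte-like cluster, was 0.402-fold, 0.408-fold and 0.837-fold. The interferon-responsive genes Slfn4 (chromosome 11, 83175186 to 83190216) and Gbp2 were at 986 against 1571 and 37.7 against 64.3 CPM in mature-like cells. The granule gene Orm1 was 0.586-fold, 0.993-fold and 0.422-fold. Fam64a, a mitotic gene of the G2/M list, was 0.504-fold, 0.836-fold and 0.429-fold. The non-coding RNA gene Snhg9 was 0.998-fold, 0.490-fold and 0.462-fold. Gabbr1, Bmf, AW112010, Adam19 and Dgcr6 made up the rest, with folds between 0.0627 and 0.911.

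The labels give a sham operation for the female, which the protocol does not mention, so whether it was operated on is open. The female library was compared with the sham male library to ask which features of marrow neutrophils differ between a female and a male with testes. It had more mature-like and fewer monocyte-like cells than the sham male, and a lower share of precursor-like cells by a smaller margin than in the orchiectomized male. S phase transcripts of precursor-like cells were higher, and so were Per1 and the secondary granule gene Chil3, and in mature-like cells most immediate early genes.

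Precursor-like cells made up 5.17% (4.76 to 5.59) of the female cells against 6.28% in the sham male, a ratio of 0.822 (0.737 to 0.917). That ratio was 0.990 without mature-like cells and doublet-like clusters in the denominator. Progenitor-like cells made up 2.82% (2.52 to 3.15), a ratio of 0.767 (0.662 to 0.887). Mature-like cells made up 32.4% (31.5 to 33.3), a ratio of 2.22 (2.10 to 2.35), with clusters 0, 5 and 7 at 15.8%, 8.44% and 8.09%. With at least 1000 UMIs per cell the ratio was 3.38, and with differing genes left out of the clustering it was 2.42. Immature-like cells made up 25.5% (24.7 to 26.4), a ratio of 0.827 (0.787 to 0.868) that was 1.043 with genes scaled within each library before clustering. Of the 3 neutrophil classes together, 8.19% were precursor-like and 51.3% mature-like. Median UMIs were 17087 in precursor-like, 5249 in immature-like and 1096 in mature-like cells, each above the sham male, and 43.4% of the mature-like cells had under 1000 UMIs.

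In precursor-like cells, S and G2/M UMIs were 124.1 (123.5 to 124.8) per 10000 UMIs, a ratio of 1.068 (1.059 to 1.076). The median gene with at least 20 UMIs in both libraries was shifted 1.086-fold, and with size factors the ratio was 0.983 (0.975 to 0.991). S phase UMIs were 41.8 per 10000, a ratio of 1.183 (1.166 to 1.199) and with size factors 1.089 (1.074 to 1.104). G2/M UMIs were 82.4 per 10000, a ratio of 1.018 (1.008 to 1.027) that was 0.937 (0.928 to 0.946) with size factors and below 1 under 2 alternatives of the clustering. Progenitor-like cells held 130.5 per 10000, a ratio of 1.045, and cluster 2 held 164.6, a ratio of 1.128. The ratio was 0.869 in cluster 1, 1.029 in cluster 4 and 1.093 in the whole immature-like class. With size factors the ratios of progenitor-like cells, cluster 2, cluster 4 and the immature-like class were 0.956, 1.006, 0.942 and 0.994. Over all kept cells the sum was 108.1 (107.9 to 108.4), a ratio of 1.046 (1.042 to 1.049), but the ratio was 0.952 with size factors and 0.946 as a mean over cells of each cell's share. After thinning, 27.2% (23.5 to 31.0) of precursor-like cells had a Mki67 UMI, against 23.8% in the sham male, and 14.5% (13.8 to 15.2) of all kept cells, against 16.9%. At full depth these shares were 86.3% and 28.9%, and mature-like cells held 1.32% after thinning. Top2a and Pcna UMIs were found in 26.6% and 22.6% of thinned precursor-like cells.

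Over all measured genes the median log2 ratio of the female to the sham male was 0.11 in precursor-like, 0.12 in immature-like and 0.021 in mature-like cells, and between −0.0026 and 0.015 with size factors. The S phase list had medians of 0.24, 0.18 and 0.23 (0.12, 0.051 and 0.23 with size factors), with 8 of 45 members past the upper limit and 0 past the lower limit in precursor-like cells, where Ung was 1.65-fold and Msh2 1.59-fold. In the same cells Pcna was at 255 against 203 CPM, Mcm5 at 245 against 199.8, Mki67 at 341 against 301 and Top2a at 364 against 339.7, which changed direction with size factors. The G2/M list had medians of 0.049, 0.12 and 0.14, the first and second of which changed sign with size factors. Histone genes had medians of −0.15, −0.12 and 0.17, and Hist1h2ae was 0.635-fold (0.599 to 0.674) in precursor-like cells.

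Primary granule genes had medians of 0.11, which changed sign with size factors, −0.082 and 0.24. In immature-like cells Mpo was at 57.6 against 48.4 CPM, below its 96.3 against 56.4 CPM in T cell-like cells, and in mature-like cells at 155 against 116 CPM, a smaller rise than in T cell-like cells, so the transcripts of other cells cannot be set apart in these classes. The T cell-like values again include cells high in S100a8. In precursor-like cells Mpo was at 9941 CPM against 7827 in the sham male, Elane at 10487 against 9659, Prtn3 at 9507 against 9310.4, Ctsg at 2497 against 2268 and Fcnb at 1047 against 909.8, with Elane and Prtn3 changing direction with size factors. Secondary granule genes had medians of 0.025, which changed sign with size factors, 0.21 and −0.20. Chil3 was 2.55-fold (2.50 to 2.60) in precursor-like and 2.41-fold (2.39 to 2.42) in immature-like cells, at 12634 against 5251 CPM in the latter. In immature-like cells Ltf was at 13999 against 10925 CPM, Ngp at 62132 against 53986, Lcn2 at 17527 against 15031 and Camp at 52242 against 55296. Tertiary granule genes had medians of −0.55, with 8 of 11 members past the lower limit, 0.13, which changed sign with size factors, and 0.14. In precursor-like cells Retnlg, of this list, was at 173 against 302 CPM, below its 854 against 1271 CPM in T cell-like cells. Transcripts of other cells therefore cannot be set apart for late genes of precursor-like cells. The mature neutrophil list had medians of −0.23, −0.22 and 0.19, and in immature-like cells 9 of 23 members lay past the lower and 1 past the upper limit. In mature-like cells Cxcl2, a neutrophil-attracting chemokine gene, was 2.78-fold (2.04 to 3.86), Retnlg was at 26770 against 18614 CPM, Il1b at 718 against 523, Cxcr2 at 1773 against 1317, Cxcr4 at 346 against 401 and Csf3r at 2231 against 2104. In the female library 5.16% of T cell-like cells had over 1% of their UMIs from S100a8, against 16.7% in the sham male.

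Granulopoiesis transcription factors had medians of 0.16, 0.21 and 0.24. Cebpb was 2.69-fold (2.55 to 2.84) in mature-like cells, Myc 1.36-fold in precursor-like cells, Gfi1 at 186 against 156 CPM in precursor-like cells and Cebpe at 791 against 697 CPM in immature-like cells. Immediate early and stress genes had medians of 0.15, 0.21 and 0.44 (0.037, 0.095 and 0.43 with size factors), with 7 of 22, 9 of 24 and 19 of 25 members past the upper limit and 0 past the lower limit, led by Fosb at 4.53-fold (3.12 to 6.72) in immature-like cells. NF-kB inflammatory genes had medians of 0.012 and 0.071, which changed sign with size factors, and 0.33 in mature-like cells, where Nfkbia was 2.04-fold. Interferon response genes had medians of −0.040, −0.046 and −0.0094. The mature-like class was made up differently, since cluster 7, with Il1b and interferon genes among its first 10, held 900 of its 3604 cells in the female. In the sham male it held 242 of 1834. Androgen and shared steroid receptor response genes had medians of 0.16, 0.23 and 0.25 (0.042, 0.10 and 0.24 with size factors), with 5 of 18, 8 of 20 and 6 of 17 members past the upper limit. In mature-like cells Per1 was 7.00-fold (5.01 to 10.1), Tsc22d3 at 573 against 335 CPM and Fkbp5 at 127 against 140 CPM. Androgen and growth factor signalling genes had medians of 0.17, 0.11, which changed sign with size factors, and 0.22.

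Mitochondrial transcripts had medians of 0.40, 0.38 and −0.66, with mt-Co2 1.48-fold in precursor-like cells and all 12 measured in mature-like cells past the lower limit. Here too, mature-like cells were shallower in the sham male. Oxidative phosphorylation genes had medians of −0.088, −0.078 and −0.082, and cytosolic ribosomal protein genes −0.048, −0.061 and 0.10. NADPH oxidase genes had medians of 0.061, which changed sign with size factors, 0.15 and 0.19, and NET and histone handling genes 0.10, which also changed sign, 0.15 and 0.27. Glycolysis genes had medians of 0.091 and 0.12, both of which changed sign with size factors, and 0.11, and Hk2 was 0.561-fold in mature-like cells. Marrow retention and egress genes had medians of 0.065, which changed sign with size factors, 0.19 and 0.24. MHC and antigen presentation genes had medians of 0.17, 0.066, which changed sign with size factors, and 0.10, and the class I gene H2-K1 was 1.38-fold (1.30 to 1.47) in mature-like cells. Apoptosis and survival genes had medians of 0.087 and 0.061, both of which changed sign with size factors, and 0.14, with the pro-apoptotic gene Pmaip1 2.33-fold in mature-like cells.

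**Figure D2:**
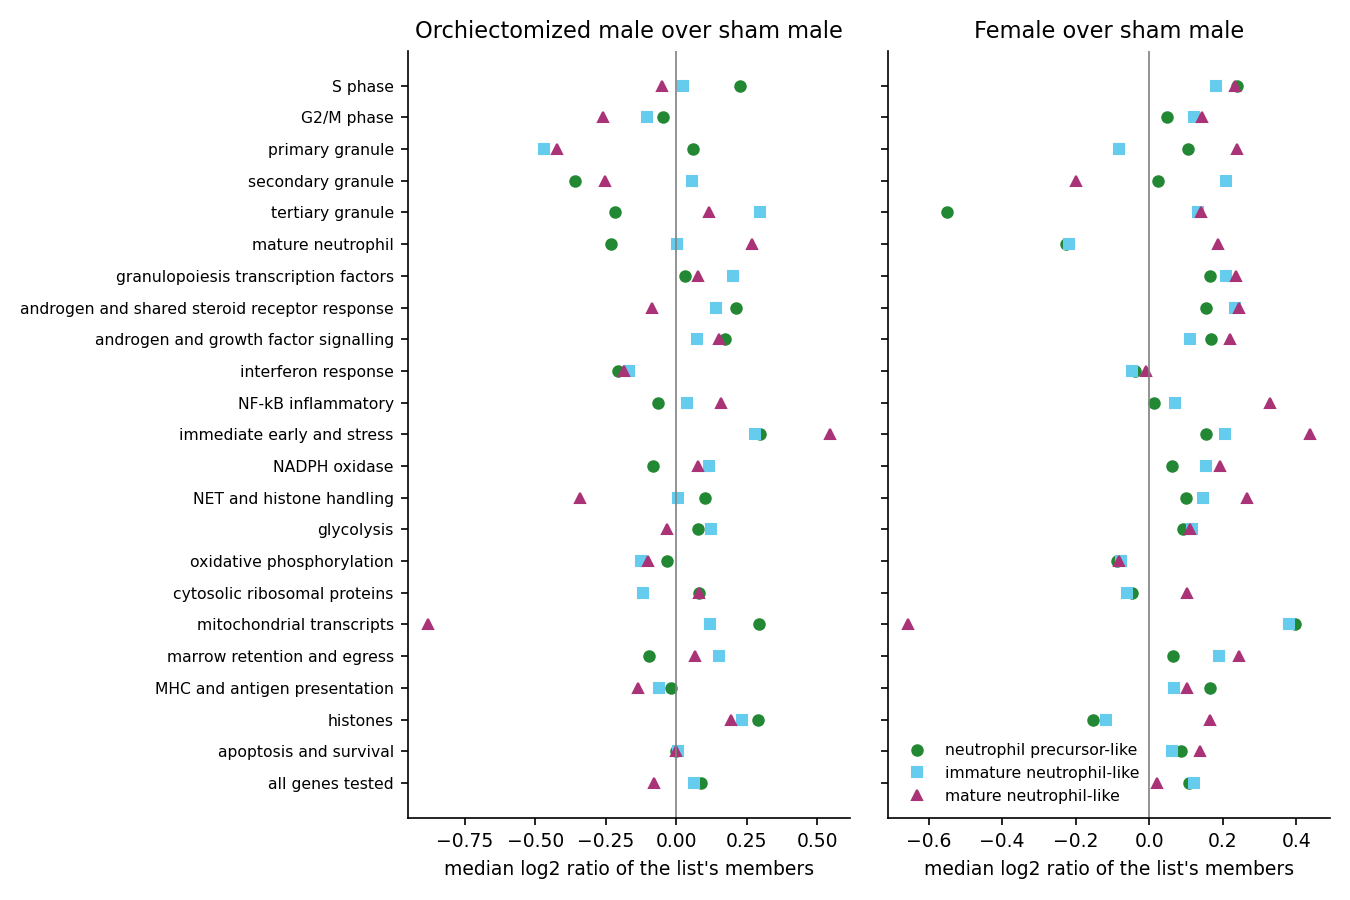
Median log2 ratio (horizontal axis) of the measured members of each gene list in precursor-like, immature-like and mature-like cells, for the orchiectomized male (left) and the female (right) against the sham male library, scaled by total UMIs and without error bars. The S phase list lay at 0.23 and 0.24 in precursor-like cells and mitochondrial transcripts at −0.88 and −0.66 in mature-like cells, and the text names the medians that changed sign with size factors.

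Of the 12 genes named higher in the female, Per1 was 2.30-fold (1.68 to 3.18) and 3.37-fold (2.62 to 4.37) in precursor-like and immature-like cells. Chil3 (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564) and the immediate early genes Fosb and Jun followed the lists above. Klf9, a glucocorticoid-induced transcription factor gene, was 2.47-fold (1.93 to 3.18) in precursor-like cells. Eif2s3x and Kdm6a, X-linked genes known to escape X inactivation, were 1.88-fold, 1.74-fold and 1.51-fold and 1.67-fold, 2.07-fold and 1.39-fold. Erdr1 was 2.06-fold to 2.21-fold. Thbs1, which encodes thrombospondin, was 3.93-fold (2.61 to 6.10) in precursor-like cells, and Camkk1, Ces1d and Lipg lay between 1.29-fold and 5.07-fold.

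Eps8l1 came first among the 12 named lower in the female, at 0.297-fold, 0.323-fold and 0.263-fold (0.164 to 0.414) in precursor-like, immature-like and mature-like cells. Wfdc17 was 0.273-fold, 0.279-fold and 0.717-fold. Gm5483 and BC100530, stefin-like genes of late neutrophils, were 0.189-fold (0.144 to 0.245) and 0.560-fold in immature-like cells. S100a6 was 0.424-fold, 0.659-fold and 0.908-fold. Snhg9 was 0.635-fold, 0.586-fold and 0.561-fold, and Fam64a 0.700-fold, 0.900-fold and 0.280-fold. Hist1h2ae, Rdh13, Dmwd, C030034I22Rik and RP23-218K15.3 made up the rest.

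**Figure D3:**
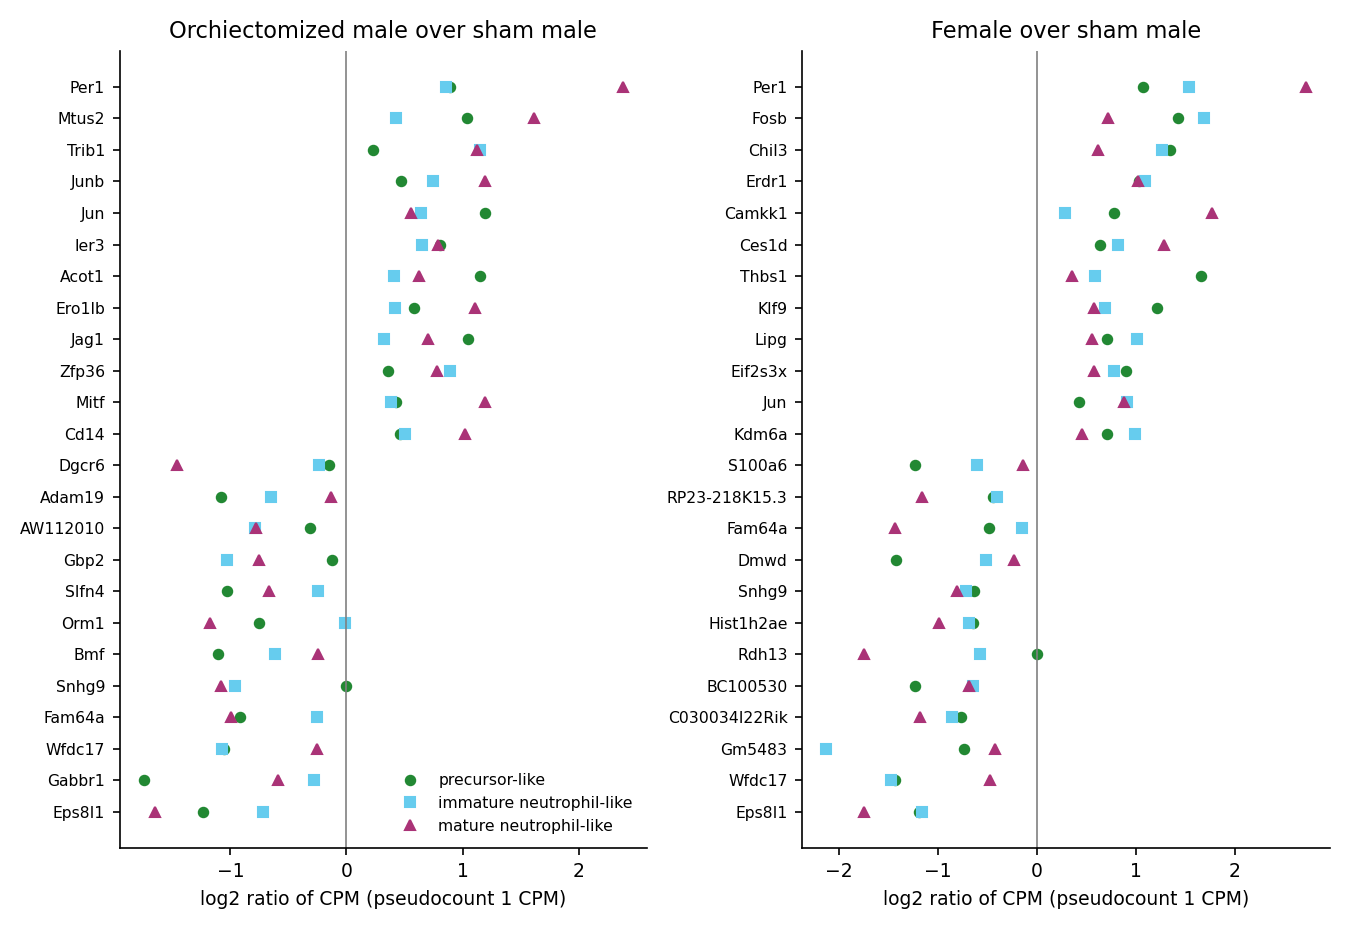
Log2 ratio to the sham male library (horizontal axis) of the genes named by the fixed rule, 1 point for each of the 3 neutrophil classes, for the orchiectomized male and the female library, with counting intervals not drawn. Per1 in mature-like cells lay farthest to the right of the genes named higher in both, at 74.7 and 94.6 CPM against 13.5 CPM in the sham male.

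The orchiectomized male was also set against the female library directly. Precursor-like cells were 0.697 (0.606 to 0.801) and mature-like cells 1.07 (1.02 to 1.13) of the female shares. S and G2/M UMIs of precursor-like cells were 0.979 (0.969 to 0.988) of the female value, or 0.993 (0.983 to 1.002) with size factors. Histone genes had a median log2 ratio of 0.39 in precursor-like cells, with 41 of 64 members past the upper limit, and interferon response genes −0.18, −0.081 and −0.28 in precursor-like, immature-like and mature-like cells. The mature-like class was made up differently, since cluster 7, with interferon genes among its first 10, held 5.53% of the orchiectomized male and 8.09% of the female cells. Secondary granule genes had a median of −0.40 in precursor-like cells and tertiary granule genes 0.33 in immature-like cells.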

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

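Results were recomputed under 17 alternatives fixed before the data were examined and 5 added after seeing the data: each library's own doublet threshold, removal of doublet scores over 0.1, leaving out mature-like cells and doublet-like clusters, leaving differing genes out of the clustering, and size factors for the cycle sums. Of 3733 values for 248 results, 3557 stayed within the spread given to them, 157 moved and 19 reversed. For list medians and single genes this spread was a fixed log2 difference of 0.322, larger than most of the list medians given above. A value that changed sign within it was therefore counted as having stayed. Among the reversals, only those of list medians had main values past the limits of fold. Another 227 values changed sign without being counted as reversed. The always followed genes entered with 660 values for 44 results, which do not cover every class and comparison in which they were followed. Of these values 39 changed sign, 6 of them with size factors. The changes of direction named above for single genes are therefore not all counted here. No value of the genes named by the rule changed sign, and 37 of their 629 moved. The rule had picked these genes for extreme means of the same sign in every class, so changes of sign were unlikely from the start. A named gene below the minimum of UMIs under an alternative was not evaluated there. No paired analysis was possible because the groups share only replicate number 1, and no result comes from a test.

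The share of precursor-like cells was below the sham male under every alternative run, with ratios from 0.567 to 0.708 for the orchiectomized male and from 0.791 to 0.990 for the female. It was 0.670 (orchiectomized male) at Leiden resolution 2, 0.662 (orchiectomized male) with differing genes left out of the clustering, and 0.708 and 0.990 without mature-like cells and doublet-like clusters. Leaving out cells from the denominator moves these 2 ratios by construction. For the other moved and reversed values below the cause was not tested.

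The mature-like share stayed higher in both libraries under every alternative run. Its ratios (orchiectomized male, female) were 3.73 and 3.38 with at least 1000 UMIs, 2.52 and 2.40 under 5% mitochondrial UMIs, 2.21 and 1.996 with doublets kept, 2.53 and 2.42 with the cycle lists kept in the clustering, 2.54 and 2.44 at resolution 0.5, 2.59 and 2.48 with 15 principal components, and 2.73 and 2.63 with each library's own doublet threshold. It was 2.23 (orchiectomized male) with genes scaled within each library, 2.23 (orchiectomized male) with doublet scores over 0.1 removed and 2.42 (female) with differing genes left out. The immature-like share reversed. For the orchiectomized male its ratio was 1.02 with doublets kept, 1.02 with 15 principal components, 1.15 with genes scaled within each library, 1.05 with each library's own doublet threshold and 1.16 without mature-like cells and doublet-like clusters. For the female it was 1.04 with genes scaled within each library.

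The S and G2/M sum of precursor-like cells reversed with size factors, to 0.976 for the orchiectomized male and 0.983 for the female. Under the other alternatives run it lay from 1.038 to 1.055 and from 1.047 to 1.089. The values that moved were 1.055 and 1.079 with each library's own doublet threshold and, for the female, 1.047 at resolution 2, 1.047 with differing genes left out and 1.089 without the 3 list members with the most UMIs. The female G2/M ratio of precursor-like cells reversed, to 0.969 at resolution 2, 0.975 with differing genes left out and 0.937 with size factors, as did the female sum of immature-like cells, to 0.994 with size factors. Over all kept cells the sums (orchiectomized male, female) were 0.978 and 1.049 with at least 1000 UMIs, 0.949 and 1.036 with doublets kept, 0.975 and 1.051 with equal cell numbers, 0.964 and 1.037 with scores over 0.1 removed, 0.933 and a reversed 0.952 with size factors, a reversed 1.015 and 1.076 without mature-like cells and doublet-like clusters, and 0.871 and a reversed 0.946 as a mean over cells. They were also 0.941 (orchiectomized male) without the 3 top list members and 1.049 (female) with each library's own doublet threshold. The Mki67 share over all kept cells was 0.923 (female) thinned to 2000 UMIs, and 0.932 and a reversed 1.008 (female) without mature-like cells and doublet-like clusters.

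Of 2112 values of list medians, 170 changed sign, 31 of them with size factors. The 3 with a main median past the limit were all for NET and histone handling genes in mature-like cells of the orchiectomized male. The median was 0.10 with at least 1000 UMIs, 0.025 at resolution 0.5 and 0.11 with members of at least 100 UMIs. Depth limits the mature-like class most, with a median of 827.5 UMIs per cell in the sham male.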

Other observations

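Cells outside the neutrophil series also differed between the libraries. B cell-like cells, led by Ebf1, Vpreb3 and Cd79a, made up 3.76% of the orchiectomized male, 2.76% of the female and 2.26% of the sham male cells, a ratio of 1.66 (1.42 to 1.96) for the orchiectomized male. They also held more cycle transcripts, with 159.2 and 144.1 against 98.8 S and G2/M UMIs per 10000. These sums include cells high in S100a8, which made up 6.6% and 6.5% of the class against 17.6% in the sham male. After thinning, the shares with a Mki67 UMI were 14.3% (10.6 to 18.8) and 14.5% (10.6 to 19.3) against 10.9% (6.99 to 16.1), with overlapping intervals. Without cells high in S100a8, the S phase and G2/M lists of B cell-like cells had median log2 ratios of 0.55 and 0.49 in the orchiectomized male, where the polymerase clamp Pcna was 2.15-fold (1.69 to 2.78), and 0.17 and 0.43 in the female. MHC and antigen presentation genes were lower in B cell-like cells of the orchiectomized male, at −0.49, with H2-Eb1 at 0.474-fold and H2-Aa at 0.543-fold. Stages within the B cell-like cluster were not set apart. The G2/M list of plasmacytoid dendritic-like cells was at 0.41 and 0.53, and their S phase list at 0.28 and 0.069. After thinning, few of them had a Mki67 UMI, with 7 of 209 in the orchiectomized male, 15 of 443 in the female and 9 of 364 in the sham male. The intervals of these shares, in which cells high in S100a8 were counted, overlapped. T cell-like cells of the female had medians of −0.66 for the G2/M list, 0.24 for the S phase list, with 13 of 32 members past the upper and 4 past the lower limit, and −0.56 for interferon response genes. At full depth, a Mki67 UMI was found in 5.71% of female and 5.85% of sham male T cell-like cells, those high in S100a8 included.

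Monocyte-like cells made up 16.7% of the orchiectomized male, 15.8% of the female and 23.1% of the sham male cells. In the female, their interferon response genes were lower, with a median of −0.34, and Ifit3 was 0.362-fold, but the interferon-rich cluster 19 of this class also held only 0.404% of the female against 1.20% of the sham male cells. Their MHC and antigen presentation list had a median of −0.22, with 5 of 12 members past the lower limit, among them H2-Aa and H2-Eb1, which also lead the conventional dendritic cluster. In the orchiectomized male, 2 heat shock genes were higher, Hspa1a at 19.9-fold (10.8 to 40.8; 15.3 against 0.766 CPM) and Hspa1b at 16.0-fold (9.97 to 27.1; 21.2 against 1.32 CPM). Macrophage-like cells, led by C1qa, made up 0.113%, 0.638% and 0.756% of the orchiectomized male, female and sham male cells. Genes in these 2 paragraphs were chosen after their values were seen.

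The tests below on the mature-like share and on Per1 were chosen after the result was seen.

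Mature-like cells had a higher share in the orchiectomized male and female libraries than in the sham male. Fewer UMIs per cell in the sham male together with the 500 UMI floor would be a technical reason, but with the floor of the deeper library raised by the ratio of depths the ratios were 2.21 (2.08 to 2.35) and 2.01 (1.89 to 2.13). With doublets kept they were 2.21 (2.09 to 2.34) and 1.996 (1.89 to 2.11), which argues against doublet removal as the whole reason. A sort gate that let in more Gr1-low cells of the sham male stays open, since monocyte-like cells were highest there (23.1%, against 16.7% and 15.8%), while T, B and NK cell-like cells together made up 6.43% (6.01 to 6.88) there, 6.37% (5.86 to 6.89) in the orchiectomized male and 7.86% (7.37 to 8.38) in the female. Differences between single mice, orchiectomy and sex stay open as untested.

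Per1 was higher in the neutrophil classes of both libraries, and in monocyte-like cells at 49.6 and 50.7 against 14.5 CPM, while it was 1.00-fold (0.434 to 2.20) and 0.860-fold in T cell-like cells. Another time of day at sampling was left undecided by the clock genes. Those of the phase of Per1 had medians of 0.20 (−0.052 to 0.31) and −0.088 (−0.22 to 0.11), with 0 and 1 of 7 past the upper limit, and those of the opposite phase 0.056 (−0.13 to 0.23) and 0.30 (0.21 to 0.40), which in the female is the reverse of what a shift towards the phase of Per1 would give. Handling stress was left undecided too. Outside the myeloid cells, the immediate early list in T, B and plasmacytoid dendritic-like cells had medians of 0.045 (−0.0034 to 0.20) and 0.086 (0.014 to 0.22). Its members went both ways, with 7 and 4 of 22 past the upper and 3 and 1 past the lower limit. In monocyte-like cells the list had medians of 0.33 and 0.30. The heat shock genes Hspa1a and Hspa1b, higher in monocyte-like cells of the orchiectomized male, were not among the 22. Glucocorticoid response genes had medians of −0.057 (−0.18 to 0.29) and 0.28 (0.20 to 0.38). These 3 cannot be told apart with 1 library per group and few members per list, and orchiectomy and sex stay open as untested.

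T, B and plasmacytoid dendritic-like cells held more S100a8 in the sham male library than in the others. Elane and Mpo did not follow this in T cell-like and plasmacytoid dendritic-like cells of the female, with Mpo at 96.3 against 56.4 CPM in T cell-like cells. Among plasmacytoid dendritic-like cells, 16.5% of the sham male, 3.14% of the orchiectomized male and 8.28% of the female had over 1% of their UMIs from S100a8. Free RNA would reach every cell, but the median sham male cell had 0.0998 of the class mean, which argues against it as the main source. As a lower background in all libraries free RNA stays open. An S100a8 UMI was found in 95.7% (sham male), 98.7% (orchiectomized male) and 99.3% (female) of plasmacytoid dendritic-like cells. Their median cells held 1704, 2088 and 1719 CPM in that order, so this background was not highest in the sham male. Doublets with neutrophils may be the source, since the tenth of cells with the most S100a8 held 83.3% of its UMIs, against 34.0% in the orchiectomized male. That share was 84.5% in the female too, so this measure sets the sham male apart from the orchiectomized male and not from the female. In other classes the gap was smaller, with 85.1% against 78.3% in T cell-like and 89.9% against 66.1% in B cell-like cells of the sham and the orchiectomized male. No biological explanation was tested.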
